A study of Mus musculus with 5 samples.

How the data were processed

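RNA sequencing of single cortical hemispheres at postnatal day 1 was labelled as 3 samples heterozygous for the Foxg1 frameshift allele Q84Pfs and 2 wild-type samples. Libraries were made with a stranded Illumina kit, per the labels' protocols. STAR 2.6.1d, RSEM 1.3.3 and the mouse build mm10 are named in the submitters' processing notes. The gene annotation behind the table is not given in the sources used here.

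The deposited table holds estimated counts per gene for 5 libraries. The 5 column names match no sample's labels and show no genotype. The name of the table sets 3 of its libraries against the other 2, which are the sizes of the labelled groups, but a file's name was not accepted as evidence of a genotype. The values and their totals per column were inspected when their unit was established, and the totals differed severalfold between libraries. The lowest totals were those of the 2 libraries that the table's name sets apart, so if that split were the genotypes, depth would be confounded with genotype. Apart from these remarks on the totals, none of the 5 columns entered a reported result. Depths per library are not reported, no test was run and the planned comparison of the genotypes with edgeR's quasi-likelihood test was not made. The results rest on the gene identifiers and symbols of the rows.

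Row identifiers were matched without version numbers to the GENCODE M21 primary assembly annotation of GRCm38, the assembly also called mm10. Coordinates are from that annotation and count from 1. The members of 33 gene lists, fixed in the plan of the genotype comparison, were looked up by exact symbol. Alternatives, chosen after the data were seen, required both identifier and symbol to be equal, accepted RefSeq synonyms, or took the GENCODE M21 symbol of each row identifier. The rule for naming genes by their test was not applied because there was no test; the genes named here are Foxg1 and example list members, picked without reference to any expression value.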

Results

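Cortical RNA was sequenced from mice at postnatal day 1 to compare animals carrying the Foxg1 knock-in frameshift allele Q84Pfs on 1 chromosome with wild-type animals. The labels gave 3 heterozygous samples and 2 wild-type samples, each from a single hemisphere. The 5 libraries in the deposited table were named by numbers that no label gives, and every name carried the allele's name, so no library was assigned to a genotype. The name of the table itself sets 3 libraries against the other 2, as many as the labels give for each genotype, but this was not taken as an assignment. No expression value, total count per library or comparison between the genotypes is reported, and the values given here describe the genes that were listed for measurement.

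Foxg1, a forkhead transcription factor of the developing forebrain, was listed in the table under ENSMUSG00000020950. In the GENCODE M21 annotation of GRCm38 the gene spans chromosome 12 from 49382660 to 49386861 on the plus strand. Its coding sequence runs from 49384486 to 49385928, a length of 1443 bases without an intron. In the spliced coding transcript this coding sequence lies wholly within exon 2, from 49384301 to 49386861. Exon 1 of that transcript, from 49383007 to 49383386, is 5′ untranslated sequence. The level of Foxg1 in each genotype was not analysed here.

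The table listed 46517 genes, each with a different identifier. Of these, 46005 identifiers (98.9%) occurred in GENCODE M21, and 512 did not. Among the matched rows, 21547 were protein-coding genes, 6321 were processed pseudogenes and 3302 were long intergenic noncoding RNA genes. A further 2280 were annotated as antisense genes and 2202 as microRNA genes. The symbol in the table was the GENCODE M21 symbol for 41803 rows and another symbol for 4202 rows.

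The table listed nearly all symbols of the 33 cell type and pathway lists chosen for this tissue in the plan of the genotype comparison. Of 597 different symbols in these lists, 588 were present, and 27 lists were complete. The 20 oligodendrocyte precursor markers were all listed, among them Olig2 and Pdgfra, as were the 20 myelin markers, among them Mbp and Plp1. All 18 upper layer neuron markers were listed, including Satb2 and Cux2, and so were 17 of 18 deep layer markers, including Bcl11b and Tbr1. The missing deep layer symbol, Diaph3, has the RefSeq synonym Diap3, which was listed. Of the 16 Cajal-Retzius cell symbols, 15 were present, including Reln, and the missing one, Tbr2, is an alias of Eomes, which was listed. The red blood cell list was the least complete, with 9 of 13 symbols present. Of its missing symbols, Epb42 has the RefSeq synonym Epb4.2, which was listed. No listed synonym was found for Hbb-b1, Hbb-b2 and Ahsp. The other Hbb symbols of that list, Hbb-bs, Hbb-bt and Hbb-y, were listed. Being listed says nothing about whether a gene was expressed or changed.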

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

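All alternatives given here were chosen after the data were seen. The number of rows matched to GENCODE M21 went from 46005 to 41803 when the symbol also had to be equal. The number of list symbols present went from 588 of 597 to 594 when RefSeq synonyms were accepted. The synonyms Ctgf, Eomes and Tenm3, found for Ccn2, Tbr2 and Odz3, were themselves list symbols already counted. For Odz3 another listed synonym, Tenm2, was also found, which was not a list symbol. The 594 are therefore symbols and not all different genes. With the GENCODE M21 symbols of the row identifiers, 591 list symbols were present. No alternative for the genotype comparison was run, because no library was assigned to a genotype. No paired analysis was possible because no column was assigned to a sample; the labels, moreover, tie a shared replicate number to no shared litter, batch or day.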
